A study of Prunus yedoensis with 90 samples.

How the data were processed

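Transcript levels were measured by RNA sequencing in apical buds and leaves of the Yoshino cherry 'Somei-yoshino', a cultivar propagated by grafting, so that its trees are copies of one clone. Per the labels, 2 trees were sampled at each of 3 sites in Japan, Fukuoka in the south, Tsukuba in the middle and Hokkaido (Sapporo) in the north, from June 2018 to spring 2019. Sampling was done around midday, tissue was kept in an RNA-stabilizing reagent, and libraries were sequenced as paired reads of 151 bases. Buds were taken on 11 dates per site, which gave 66 libraries, and leaves on the first 4 of these dates, which gave 24 libraries. The labels' protocol states a different RNA extraction for leaves and for buds, so tissue and extraction cannot be told apart in any comparison of the tissues. The same protocol, given for bud libraries too, also speaks of the sequenced RNA as taken from leaves, and tissue was read from the tissue label.

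The authors deposited TPM values (a unit scaled for gene length and library total) in a table of 95076 gene IDs by 90 libraries. A second deposited table held the same TPM values for the 58074 genes whose TPM summed over all libraries exceeded 1. Every library summed to the same total, so the tables hold no sequencing depth, and no counting interval could be given. In all, 28911 genes were at 0 in every library. The submitters' processing notes name fastp 0.20.0, STAR 1.5.2 and StringTie 1.3.5, with no role or setting for any of them. The genome build and the annotation are not given in the sources used here. The gene IDs fall into 48280 with SPA and 46796 with SPE in the ID, and the sources used here do not explain these letters.

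The files do not pair the IDs with gene names: 0 IDs matched a name in the 13 lists of 149 genes that were fixed in advance. The list tests were therefore not run, and genes are given by ID only. How reads shared by near-identical copies were divided is not given in the sources used here, so levels of closely similar IDs are uncertain.

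Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend and robust options off), with Benjamini-Hochberg adjustment over the genes tested. Genes entered a fit when their mean TPM over the fitted libraries was at least 1, which left 40161 genes for buds, 35534 for leaves and 39310 for both tissues. A gene was called when its adjusted p was under 0.05 and its change was at least 1 on the log2(TPM + 1) scale, a 2-fold change that is understated for genes of low TPM. For F tests over several groups, the range between the highest and the lowest mean had to reach 1. Tables were read with the R package data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

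The buds were fitted with 1 mean for each of 33 combinations of site and date, each with 2 trees, and seasonal contrasts were averaged over the 3 sites with equal weight, 6 trees against 6. The 10 calendar months from June to March had buds of all 6 trees. The Fukuoka collection of 29 August and the April collections of the other sites stayed out of the monthly contrasts. Leaf and bud were compared on the means of each tree over its first 4 collections, with site as a covariate. Sites were compared within each month, in their seasonal changes, and on means of each tree over the 10 months. Leaf libraries were compared between collection 4, from 29 August to 7 September, and collection 1, from 4 to 7 June. Replicate numbers mark the same tree at every date, so they pair libraries by design. As a check, the difference between the 2 trees of a site was correlated across genes between dates, and the median r was 0.0433 in Fukuoka, 0.0533 in Tsukuba and 0.0892 in Hokkaido.

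Named genes followed a rule set before the data were examined: in each comparison, the 2 called genes with the largest rise and the 2 with the largest fall among genes with a mean TPM of at least 5 whose change had the same sign in all trees, or in every pair of trees of the 2 sites compared. Library numbers in the labels fall into series that change between autumn and winter in 4 trees and stay the same through the year in 2 trees. Alternatives covered the pseudocount, the filter, quantile and median scaling between libraries, the eBayes options, a block for the tree, the library series, the collection number in place of the calendar month, and the omission of each tree in turn.

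The fits were tested on simulated TPM with the genes' real bud means, spreads capped for the noisiest genes, and 200 genes changed per size. Noise was drawn as normal, with no other seasonal or site differences. Changed genes were drawn from those at about 5 TPM or more in buds, so the recoveries do not cover lower genes. At a change of 2 on the log2 scale, October minus July recovered 100% of the changed genes with 3 false calls among 36404 unchanged genes. Leaf minus bud recovered 100%, leaf collection 4 minus 1 recovered 99.0%, leaf change minus bud change recovered 98.0%, and Hokkaido minus Tsukuba in tree means recovered 99.0%. For the site difference of October minus July, 87.0% were recovered at that size, and for Tsukuba minus Hokkaido in April 97.5% were.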

Results

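The series followed transcript levels in apical buds and leaves of 6 clonal Yoshino cherry trees through the year, to describe the seasonal course of gene expression around bud dormancy at 3 sites from south to north. The 66 bud libraries cover 11 dates at each site and the 24 leaf libraries cover the first 4 of them, with 2 trees per site and date. The trees are separate plants of one clone, so the spread between them holds growing conditions and technical variation but little genetic variation. Between 35471 and 40376 genes per bud library and between 33242 and 35300 genes per leaf library had a TPM over 1. The depth of the libraries is unknown, since TPM keeps none. Across genes, the 2 trees of a site on a date correlated in buds with r between 0.935 and 0.984 (median 0.977, 33 pairs) and in leaves with r between 0.918 and 0.980 (median 0.969, 12 pairs).

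Bud libraries lay along a seasonal course in a principal component analysis. The first component held 38.8% of the variance and ran from summer to midwinter, and the second held 17.8%, with April buds and Fukuoka buds of March at its lower end and Tsukuba buds of October at its upper end.

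**Figure D1:**
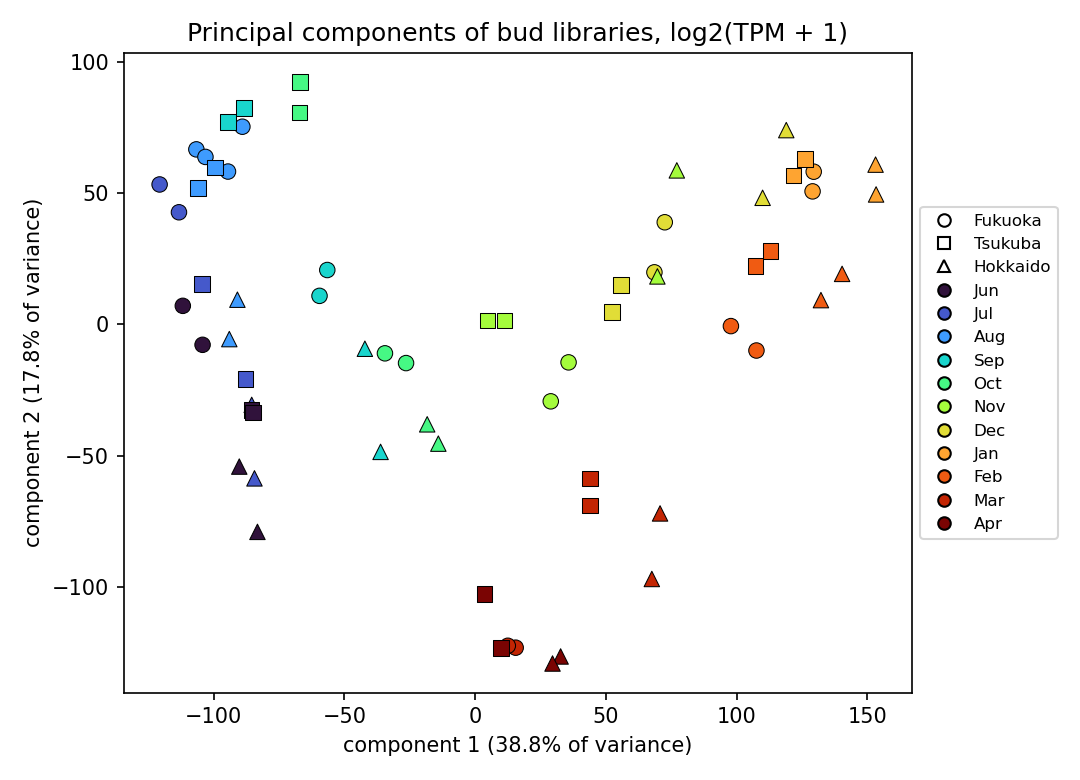
Principal components 1 (38.8% of variance, horizontal axis) and 2 (17.8%, vertical axis) of log2(TPM + 1) in the 66 bud libraries, 1 point per library, coloured by month and shaped by site. Summer libraries lie on the left, midwinter libraries on the right, and April libraries and the Fukuoka libraries of March at the bottom, while March libraries of the other sites overlap June and July libraries of Hokkaido on component 2.

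Leaves differed from buds collected on the same dates in 14542 of 39310 genes, 4701 higher and 9841 lower in leaf. The largest rises were those of CYE_r3.1SPE8_g015290.1, with 1092 ± 199 TPM in leaf and 1.23 ± 0.600 TPM in bud (SD, n = 6 trees; log2 change 8.96, SE 0.14), and of CYE_r3.1SPA8_g013090.1, with 1208 ± 280 TPM against 1.58 ± 0.641 TPM (log2 change 8.88, SE 0.15). The largest falls were those of CYE_r3.1SPA6_g047300.1, at 13103 ± 2818 TPM in bud and 66.6 ± 149 TPM in leaf, and of CYE_r3.1SPA6_g034580.1, at 7612 ± 877 TPM in bud and 70.3 ± 122 TPM in leaf. For the former, the change per tree ran from -13.69 in Tsukuba replicate 2 to -9.37 in Hokkaido replicate 1 on the log2 scale. Fewer genes had a TPM over 1 in leaf (34153 ± 490, SD over 6 trees) than in bud (38420 ± 438), and the 100 most abundant genes held 26.7 ± 1.14% of the TPM in leaf and 15.8 ± 1.27% in bud. The median change of all genes tested was -0.43 on the log2 scale, and the split between higher and lower genes depended on the scaling: 32.3% of the calls were higher in leaf as deposited, 51.1% after quantile normalization and 50.4% after median scaling. Per the labels' protocol, leaf and bud RNA were also extracted by different methods.

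From early June to late summer, 3462 of 35534 genes changed in leaves, 1637 rising and 1825 falling between collections 1 and 4. CYE_r3.1SPA1_g039890.1 rose from 0.606 ± 0.976 to 106 ± 55.6 TPM (SD, n = 6 trees; log2 change 6.06, SE 0.18), and CYE_r3.1SPE0_g005820.1 rose from 1.37 ± 1.12 to 91.5 ± 87.6 TPM. CYE_r3.1SPE3_g023280.1, at 636 ± 894 TPM in collection 1, fell by -6.53 (SE 0.83) on the log2 scale, and CYE_r3.1SPE3_g026120.1 fell from 192 ± 183 to 29.7 ± 72.7 TPM, both in all 6 trees, as the naming rule required. In buds over the same dates 3145 of 39310 genes changed. The change itself differed between the tissues in 4800 genes, of which 2887 changed more positively in leaf and 1913 more positively in bud. The median of all genes was 0.15 in the leaf change and 0.21 in the difference between tissues. The direction of the leaf changes was not stable: median scaling moved the share of calls that rose from 47.3% to 34.4%, while by adjusted p alone 9769 genes rose and 4642 fell. For leaf collection 4 minus 1, more genes also rose than fell with a pseudocount of 0.1 (2493 and 2388) and with a mean TPM of at least 5 (1100 and 930). The share of genes with the more positive change in leaf went from 60.1% to 40.9% with median scaling and to 46.1% with quantile normalization, so it has no direction apart from the scaling.

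Over the year, bud levels of 23018 of 40161 genes (57.3%) differed between calendar months, with a median range of 1.58 between the highest and lowest month on the log2 scale. The range reached 3 in 2476 genes and 5 in 355 genes. The highest mean fell in March for 5468 genes (23.8%), in February for 4144 (18.0%), in June for 3765 (16.4%) and in January for 2975 (12.9%), but in November for 375 genes (1.63%). The lowest mean fell in January for 7241 genes (31.5%) and in August for 4428 (19.2%). These months were taken from levels as deposited and were not repeated after scaling, which turned the direction of the step from January to February. January also had the fewest genes with a TPM over 1, 36402 ± 585 per library (SD, n = 6), and March the most, 39814 ± 622. The 100 most abundant genes held 19.2 ± 1.91% of the TPM in January and 12.0 ± 1.66% in March.

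**Figure D2:**
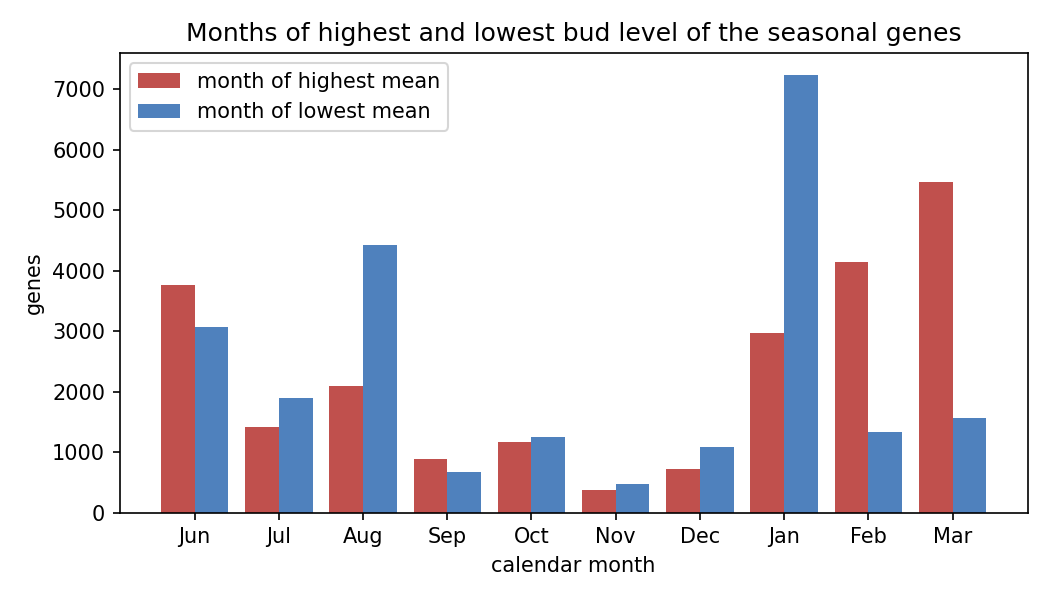
Number of genes (vertical axis) by the calendar month (horizontal axis) of their highest and of their lowest mean bud level, for the 23018 genes called between months, each mean taken over 6 trees. January is the most frequent month of the lowest level (7241 genes) and March that of the highest (5468 genes). Levels are as deposited, with no scaling between libraries.

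Among the 9 steps between consecutive months, February to March changed the most genes, 4686, with 3471 rising and 1215 falling. October to November changed 2181 genes (888 rising, 1293 falling) and December to January 2087 genes (473 rising, 1614 falling). The step January to February changed 1224 genes, 67.6% of them rising as deposited but 40.2% after median scaling and 43.1% after quantile normalization. The other steps changed between 476 genes, from June to July, and 840 genes, from September to October. Without Tsukuba replicate 2, the step from June to July held 280 genes.

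**Figure D3:**
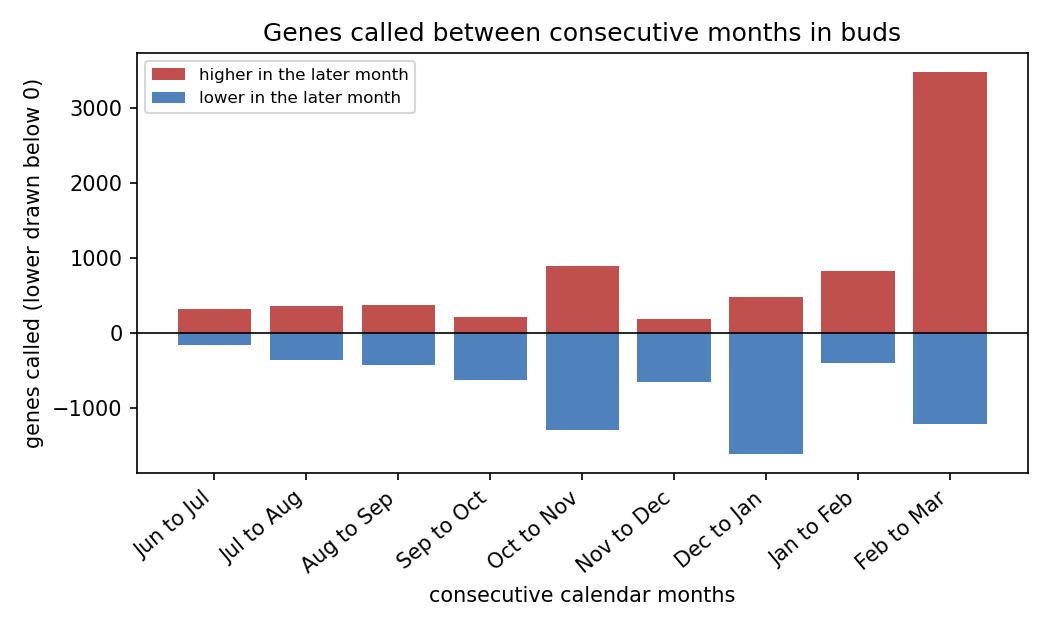
Genes called between consecutive calendar months in buds (vertical axis, number of genes; horizontal axis, pair of months), with genes higher in the later month drawn above 0 and genes lower in it drawn below. The bar from February to March is the longest, with 3471 genes higher and 1215 lower.

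From July to October 3379 genes changed in buds averaged over the sites, 1211 rising and 2168 falling. Without the minimum change the direction turns, with 11202 genes rising and 8192 falling by adjusted p alone. CYE_r3.1SPE0_g033290.1 rose from 0.774 ± 0.751 TPM to 140 ± 86.5 TPM (SD, n = 6 trees; log2 change 6.08, SE 0.37), and CYE_r3.1SPA7_g025290.1 from 3.96 ± 1.75 to 410 ± 220 TPM (log2 change 6.01, SE 0.40). CYE_r3.1SPE3_g011810.1 fell from 744 ± 532 to 2.68 ± 1.43 TPM, a log2 change of -7.40 (SE 0.26). CYE_r3.1SPA3_g011710.1 fell from 113 ± 108 to 2.07 ± 1.23 TPM, a log2 change of -4.90 (SE 0.28). The naming rule required the same direction in all 6 trees, so that agreement is no separate result, and limma's adjusted p was 1.75e-14 or lower. In the 2 trees of a single library series, fitted with 1 mean per month for both sites, 385 genes were called, 60 of them rising. CYE_r3.1SPA7_g025290.1 was not called there.

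From October to January 9319 genes changed, 3323 rising and 5996 falling. CYE_r3.1SPE0_g020130.1 rose from 0.285 ± 0.568 to 639 ± 225 TPM (log2 change 8.96, SE 0.30) and CYE_r3.1SPE0_g010980.1 from 0.190 ± 0.344 to 438 ± 151 TPM (log2 change 8.48, SE 0.29). CYE_r3.1SPA8_g014780.1 fell from 221 ± 168 to 0.0482 ± 0.118 TPM and CYE_r3.1SPA8_g014790.1 from 187 ± 106 to 0.392 ± 0.422 TPM (n = 6 trees each). The share of falling genes was 66.5% of 8929 calls within Fukuoka and 67.8% of 12327 calls within Hokkaido, but 47.5% of 11133 calls within Tsukuba. The Tsukuba share depends on the scaling, at 64.1% after median scaling and 53.4% after quantile normalization. In the 2 trees of a single library series, 1 each from Tsukuba and Hokkaido and fitted with no site means, 4994 genes were called and 50.4% of them fell.

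From January to March 8464 genes changed, 6484 rising and 1980 falling. CYE_r3.1SPA0_g014220.1 rose from 1.18 ± 1.06 to 607 ± 499 TPM (SD, n = 6; log2 change 7.81, SE 0.51), and CYE_r3.1SPA3_g020470.1 from 0.0907 ± 0.222 to 115 ± 64.6 TPM. CYE_r3.1SPE0_g033290.1, which had risen by October, reached 2032 ± 1289 TPM in November and 3306 ± 357 TPM in January, and fell to 748 ± 242 TPM in February and 49.0 ± 52.3 TPM in March. CYE_r3.1SPE1_g004300.1 had nearly the same levels, 3270 ± 367 TPM in January and 50.9 ± 53.6 TPM in March, so the 2 IDs may share reads and neither level is certain on its own. The median change of all genes was 0.18 on the log2 scale, and the share of rising genes among the calls was 76.6% as deposited, 58.7% after quantile normalization and 63.6% after median scaling. With the collection number in place of month, March minus January called 4378 genes. In Fukuoka that setting compared 14 February with 19 December, so its count is not one of March minus January there.

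**Figure D4:**
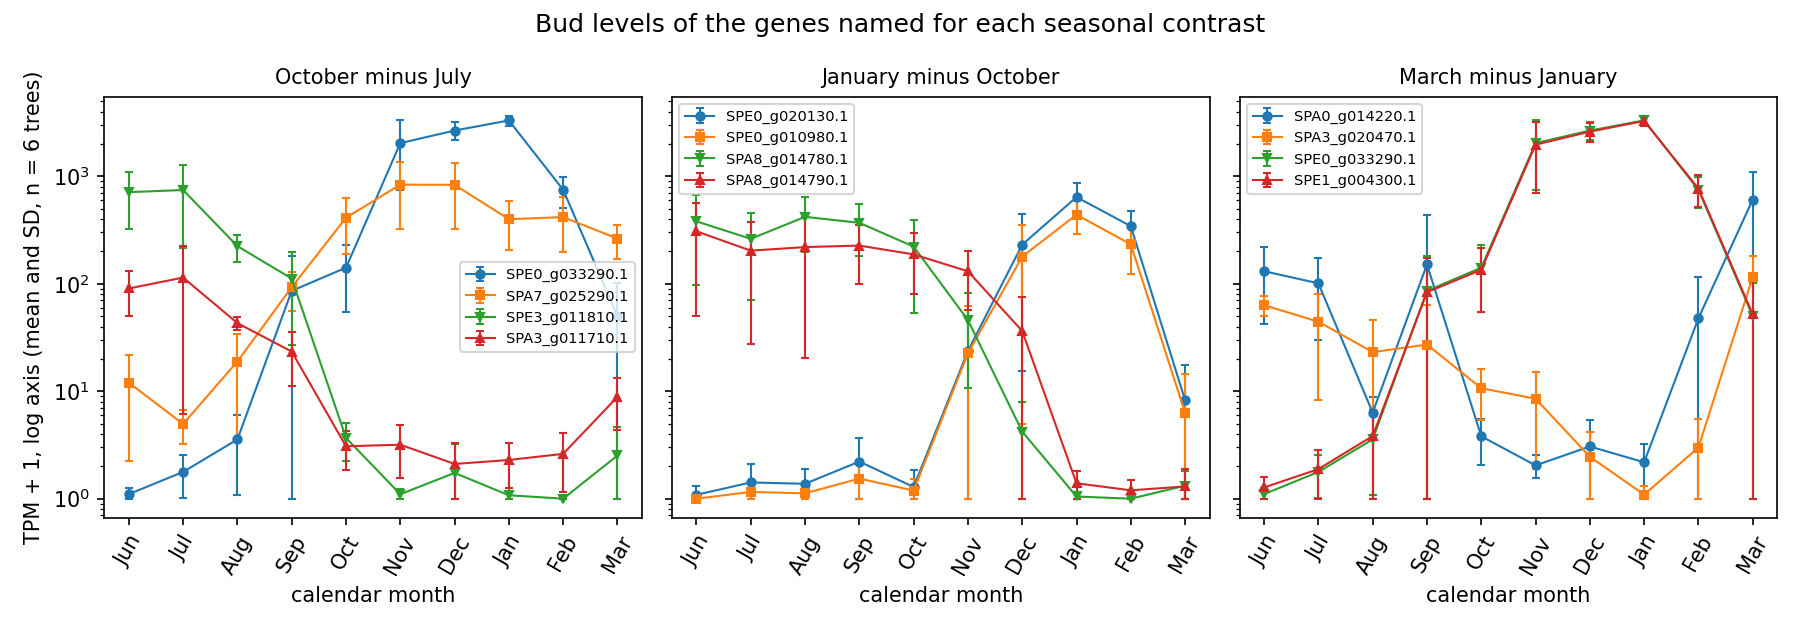
Mean TPM + 1 in buds (vertical axis, log scale; bars show the SD over 6 trees) by calendar month (horizontal axis) of the 4 genes named for each of 3 seasonal contrasts, 1 panel per contrast, with IDs shown without their shared start. CYE_r3.1SPE0_g033290.1 goes from 0.774 TPM in July to 3306 TPM in January and 49.0 TPM in March.

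Genes called lower in December than in October were called higher in March than in January more often than independent lists would give. December minus October and March minus January share no library: 2915 genes fell and 1685 rose in the first. Of the genes that fell in it, 1777 rose from January to March, where 471 would be shared by independent lists, and 40 fell again, where 144 would be. Of those that rose in it, 824 fell from January to March, where 83.1 would be shared by independent lists.

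Within calendar months the 3 sites differed most in October, with 10105 genes, and September, with 9153 genes, and without Hokkaido replicate 2 the order of these months turned (10514 and 10599). From June to August between 3948 and 6092 genes differed per month, and from November to March between 4111 and 6442. Sampling dates differed between sites within a month, in October by 17 days between Tsukuba (7 October) and Fukuoka (24 October). The gap was wider in September, from 5 September in Tsukuba and 7 September in Hokkaido to 26 September in Fukuoka. The counts of these months therefore cannot part site from date.

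Seasonal changes differed between sites. For October minus July, 14603 genes differed in their change, and Tsukuba differed from Fukuoka in 13068 genes (3403 with a more positive change in Tsukuba), Hokkaido from Tsukuba in 7231 and Hokkaido from Fukuoka in 3319. Without Tsukuba replicate 1 Hokkaido differed from Tsukuba in 4452 genes, and without Fukuoka replicate 1 it differed from Fukuoka in 1316. Across genes the changes in Tsukuba and in Fukuoka were uncorrelated (Pearson r = -0.0057), while those in Hokkaido and Fukuoka had r = 0.527 and those in Hokkaido and Tsukuba r = 0.358; genes are not independent replicates. Of the 2544 genes that rose within Tsukuba, 323 rose and 518 fell within Fukuoka, against 226 and 170 for independent lists. Of the 4551 that fell within Tsukuba, 680 fell and 625 rose within Fukuoka, against 303 and 405. Of the 2450 that rose within Hokkaido, 1119 rose and 334 fell within Fukuoka, against 218 and 163, and of the 3175 that fell within Hokkaido, 1280 fell and 15 rose within Fukuoka, against 212 and 282. These lists are as deposited, and median scaling moved the Fukuoka changes from 3573 rising and 2677 falling to 1510 and 3915, and the Tsukuba changes to 3454 and 3202. Without Fukuoka replicate 1 the Fukuoka changes were 2185 rising and 1710 falling, and with the collection number in place of month 2878 in all. The collection number took 26 September for October in Fukuoka, and with it Tsukuba differed from Fukuoka in 9539 genes. For Tsukuba against Fukuoka the median over all genes was -0.50. After median scaling 9667 genes were called, 5552 of them with the more positive change in Tsukuba. CYE_r3.1SPE3_g011810.1 changed by -8.70 on the log2 scale in Tsukuba, -5.71 in Fukuoka and -7.79 in Hokkaido (limma adjusted p of the difference 0.000691).

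For January minus October 11474 genes differed between sites in their change, and the changes correlated across genes with r between 0.641 and 0.833. For the site difference of March minus January 5870 genes were called, with r between 0.741 and 0.810. Without Fukuoka replicate 1 the latter count was 3461, without Fukuoka replicate 2 it was 3847, and with the collection number in place of month it was 11271. With the collection number, 14 February and 19 December stood for March and January in Fukuoka, so that count compares other months between sites. CYE_r3.1SPE0_g033290.1 changed from January to March by -11.27 in Fukuoka, -6.17 in Tsukuba and -5.33 in Hokkaido on the log2 scale (limma adjusted p of the difference 2.31e-05). The 2 genes with the largest rise from October to January did not pass the test of a site difference: CYE_r3.1SPE0_g020130.1 rose by 8.47 in Fukuoka, 9.10 in Tsukuba and 9.31 in Hokkaido, and CYE_r3.1SPE0_g010980.1 by 7.85, 8.67 and 8.92.

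Averaged over 10 months, levels differed between sites in 1062 of 40081 genes, with 2 trees per site as the replicates. Hokkaido differed from Tsukuba in 901 genes (192 higher, 709 lower in Hokkaido), from Fukuoka in 391 (89 higher, 302 lower), and Tsukuba from Fukuoka in 232 (205 higher, 27 lower). CYE_r3.1SPE7_g016510.1 had 168 ± 27.9 TPM in Tsukuba and 24.2 ± 9.74 TPM in Fukuoka (SD, n = 2 trees), and CYE_r3.1SPA7_g023430.1 had 161 ± 29.1 and 26.4 ± 10.1 TPM. CYE_r3.1SPA2_g034430.1 had 26.0 ± 24.8 TPM in Hokkaido and 583 ± 26.7 TPM in Fukuoka, and CYE_r3.1SPE8_g020900.1 had 35.2 ± 9.71 and 119 ± 9.84 TPM. CYE_r3.1SPE3_g017980.1 had 29.6 ± 11.9 TPM in Hokkaido and 214 ± 33.1 TPM in Tsukuba, a log2 change of the monthly mean of -3.32 (SE 0.07), and CYE_r3.1SPA8_g016120.1 had 11.6 ± 1.40 and 121 ± 2.50 TPM. CYE_r3.1SPE4_g003620.1 was higher in Hokkaido than in Tsukuba by 1.83 (SE 0.13) on the log2 scale averaged over months, with 1381 ± 404 and 770 ± 85.2 TPM.

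Counts between sites depended on single trees. Tsukuba minus Fukuoka called 92 genes without Fukuoka replicate 2, 48 without Tsukuba replicate 1 and 53 without Tsukuba replicate 2, and Hokkaido minus Fukuoka called 624 without Hokkaido replicate 1. Among the other named genes, calls ended without at least 1 tree for CYE_r3.1SPA7_g023430.1, CYE_r3.1SPA0_g168420.1 and CYE_r3.1SPA0_g014300.1 in Tsukuba minus Fukuoka, for CYE_r3.1SPA5_g015000.1 and CYE_r3.1SPE0_g050770.1 in Hokkaido minus Fukuoka, and for CYE_r3.1SPE3_g029850.1 in Hokkaido minus Tsukuba. Site and anything else that differs between sites cannot be separated with these trees.

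In April, Tsukuba buds of 4 April differed from Hokkaido buds of 8 April in 867 genes, 412 higher and 455 lower in Tsukuba. CYE_r3.1SPA4_g020690.1 had 85.5 ± 49.6 TPM in Tsukuba and 1.57 ± 0.911 TPM in Hokkaido (SD, n = 2 trees), and CYE_r3.1SPE5_g004410.1 had 178 ± 2.70 and 9.37 ± 4.09 TPM. CYE_r3.1SPA2_g038830.1 was listed at 0 in both Tsukuba trees and at 1002 and 5777 TPM in the Hokkaido trees, and CYE_r3.1SPE0_g107890.1 at 0 in both Tsukuba trees and at 454 and 2351 TPM in the Hokkaido trees. From March to April 4422 genes changed within Tsukuba and 1635 within Hokkaido, and the difference between these changes was not tested. The direction was not stable: in Tsukuba 1560 rose and 2862 fell as deposited, but 2487 rose and 1569 fell after median scaling and 2222 and 1824 after quantile normalization. In Hokkaido 959 rose and 676 fell, but 419 rose and 567 fell without Hokkaido replicate 2, and without Tsukuba replicate 2 the Tsukuba count was 2451. Without Hokkaido replicate 2 the April comparison called 526 genes.

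Buds of one site resembled those of another on different calendar dates. Across genes, both Hokkaido trees of 9 July and of 13 August correlated best with Fukuoka buds of 7 June (r = 0.952 and 0.955 in July, 0.971 and 0.971 in August), and those of 7 September with Fukuoka buds of 24 October (r = 0.945 and 0.937). The collection of 7 June was the first in Fukuoka, so an earlier match for the July buds could not be seen. Both Hokkaido trees of 8 November were closest to Fukuoka buds of 19 December. Both Tsukuba trees of 7 October were closest to Fukuoka buds of 1 August (r = 0.927 and 0.932), and less close to Fukuoka buds of the same month (r = 0.886 and 0.887). For the mean of the 2 trees, r was 0.937 with 1 August and 0.933 with 29 August. With Fukuoka levels interpolated between dates, the best match lay only 28 and 29 days earlier in the year (r = 0.931 and 0.939).

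**Figure D5:**
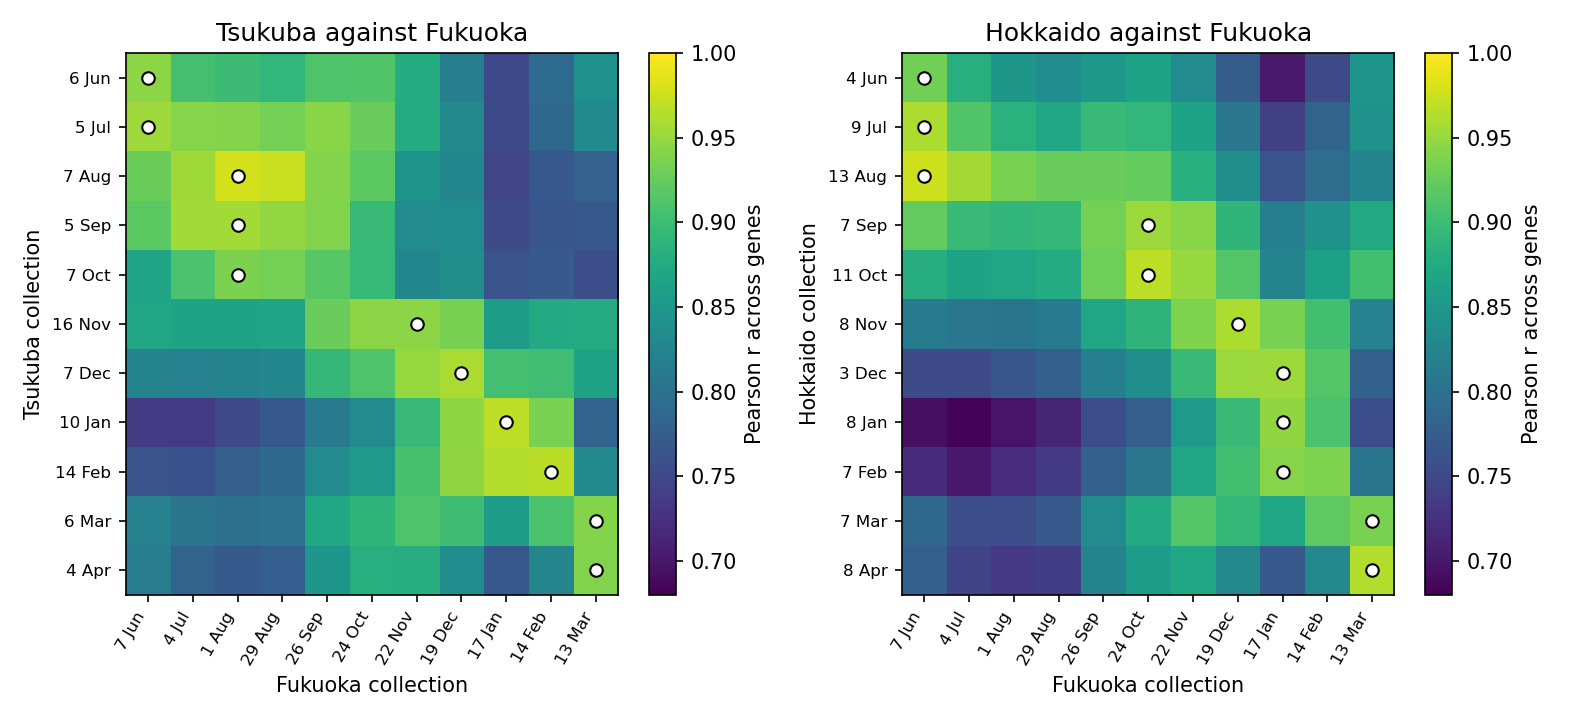
Pearson r across genes of mean log2(TPM + 1) between each Tsukuba (left) or Hokkaido (right) bud collection (vertical axis, date) and each Fukuoka collection (horizontal axis, date), with r as colour and a white dot on the highest r of each row. Dots of Hokkaido summer collections sit at 7 June in Fukuoka, and the dot of the Tsukuba collection of 7 October sits at 1 August. Dots of the Tsukuba collections from November to March sit in the same month in Fukuoka.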

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

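The tests of a mislabelled library and of a few genes taking most of the total, 2 of the 3 tests of the library series, and the overlap of calls between scalings were chosen after the results were seen; the other tests were set before.

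The changes that differed between sites were the largest group of results here. For October minus July 14603 genes differed in their change between sites, for January minus October 11474 and for March minus January 5870, each by limma's test of the difference. Leaf change minus bud change differed in 4800 genes. Among the named genes, the change over sites spanned 3.75 on the log2 scale for CYE_r3.1SPE0_g033290.1, 3.00 for CYE_r3.1SPE3_g011810.1 and 3.22 for CYE_r3.1SPA3_g011710.1 in October minus July. It spanned 2.32 for CYE_r3.1SPA8_g014780.1 in January minus October. In March minus January it spanned 5.93 for CYE_r3.1SPE0_g033290.1 and 5.93 for CYE_r3.1SPE1_g004300.1, whose levels are nearly equal. One tree stood far from the other 5 in 1 of 20 sets of named changes, about the rate chance gives: CYE_r3.1SPA7_g025290.1 rose by 2.80 on the log2 scale from July to October in Tsukuba replicate 2 and by 6.12 or more in the other trees.

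The changes from July to October in Tsukuba and Fukuoka buds were uncorrelated across genes, although the called genes overlapped in both directions more than independent lists would. The r of 0.968 between the 2 Tsukuba trees of 7 October lay above the lowest r of the other pairs (0.935), and these trees lie in different library series. This bound could miss a library of a neighbouring date, since Tsukuba buds of September and October had r = 0.960. Each of the 2 October libraries was, however, the closest bud library to the other, which argues against a single mislabelled October library. For 5 July the 2 Tsukuba trees had r = 0.952. Replicate 1 was closest to Tsukuba buds of 6 June and replicate 2 to Fukuoka buds of 4 July, and a mislabelled July library was not tested. Scaling is argued against as the whole cause: of 13068 genes called in Tsukuba minus Fukuoka, 7518 were called in the same direction with median scaling, among 9667 in all. The split between directions does depend on scaling. With quantile normalization r was 0.00904, but a shift of all genes of a library leaves r unchanged, so r could hardly move and does not test scaling. Replacing the Fukuoka collection of 24 October by that of 26 September left r between the changes at 0.0357, under the bound set before for the date within the month. The calls in Tsukuba minus Fukuoka went from 13068 to 9539 with that date. No other date was tried, so the date within the month is not excluded. A shared error in both Tsukuba libraries of 7 October was not tested, and a real difference between the sites stays open as a hypothesis. The Tsukuba October buds correlated with r = 0.960 with those of September at that site and with r = 0.906 with those of November.

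More genes fell than rose from October to January among changes of at least 2-fold, while by adjusted p alone 14129 genes rose and 14406 fell. Scaling left the share of fallen genes at 56.8% or more, against 64.3% as deposited, and the TPM left to genes outside the 100 most abundant changed by -0.042 on the log2 scale, far from a 2-fold change. The prediction set before for the library series as the cause was met, since 50.4% of the called genes fell in the 2 trees of one series, and in the other trees of the same sites, a comparison added after seeing this, 56.9% fell. A further test by tree, chosen with all of these values in view, went the other way: 65.4% of the genes that changed by 1 or more on the log2 scale fell in the Hokkaido tree of one series and 68.2% in the other Hokkaido tree, but 46.8% and 47.8% in Tsukuba (as deposited; 64.1% of the Tsukuba calls fell after median scaling), and with series and tree in the fit 64.6% of the called genes fell. No Fukuoka tree is among the 2 trees of one series, and 66.5% of the calls within Fukuoka fell. The 50.4% therefore cannot part the series from the mix of sites. In Tsukuba and in Hokkaido, the tree with and the tree without a change of series had similar shares. Both Fukuoka trees changed series, so no such comparison exists there. The tests disagree, so the series stays open as an explanation, beside the hypothesis that the excess of falls is biological.

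More genes were lower than higher in leaf. This split is what scaling could give: 48.9% of the calls were lower in leaf after quantile normalization, against 67.7% as deposited. The TPM left to genes outside the 100 most abundant was lower in leaf by 0.20 on the log2 scale (-0.20), under a 2-fold change. The median change of all genes was only -0.43, however, and scaling evened the split. A part of the split from the most abundant genes is therefore not excluded. Whether leaf held fewer active genes or the scale of the 2 tissues differed cannot be told apart from these values, and per the labels' protocol, which is not consistent on the source of the sequenced RNA, the extraction method differed between them.

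Regrouping the libraries by chance did not reach the counts that compare groups of 6: 1 of 100 regroupings within sites, the real one, gave as many genes in each case. Regrouped libraries carry the real changes into the spread within groups, which lowers their counts. The comparison therefore gives no rate of false calls. The real and the highest other counts were 14542 and 4515 for leaf minus bud, 3379 and 2464 for October minus July, 9319 and 5352 for January minus October, and 8464 and 5006 for March minus January. They were 3462 and 2523 for leaf collection 4 minus 1, 4800 and 3476 for leaf change minus bud change, 23018 and 4535 for any month, and 13837 and 10830 summed over the monthly steps. Among the 31 splits that part both libraries of every tree, the highest other counts were 0 for leaf minus bud, 2324, 5178 and 4687 for the seasonal contrasts in the order above, 2257 for the leaf collections and 3476 for leaf change minus bud change. The remaining splits leave both libraries of at least 1 tree in one group.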

How the results depend on the processing

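The 2 tables give no depth, so what depth limits is unknown. With a replicate block for the tree, every count stayed within 1.5 times of that without it (3383 genes for October minus July, 9326 for January minus October, 8471 for March minus January, 14541 for leaf minus bud, 952 for April) and no named gene lost its call; the site means have no trees to pair. With the library series added to the block, January minus October called 9732 genes. Quantile and median scaling, the eBayes options and the reduced table also left every main count within 1.5 times, and no named change reversed under any setting. The following moved further; the cause was not tested except where the setting itself gives it. A pseudocount of 5, which shrinks changes of low genes, gave 7698 genes for leaf minus bud, 12327 for any month in buds, 1381 for October minus July, 4415 for January minus October, 3968 for March minus January, 5573 calls over the monthly steps and 26835 over sites within a month. It gave 8041 for the site difference of October minus July, 5670 for the site difference of January minus October, 2954 for the site difference of March minus January, 443 for Tsukuba minus Hokkaido in April, 446 for any site in tree means, 1343 for leaf collection 4 minus 1 and 2116 for leaf change minus bud change. A pseudocount of 0.1, which widens them, gave 5071 for October minus July, 24516 over the monthly steps and 2125 for site means. A mean TPM of at least 5, which tests fewer genes, gave 9551 for leaf minus bud, 15213 for any month, 2165 for October minus July and 2030 for the leaf collections. Adjusted p alone, with no minimum change, gave 32228 for leaf minus bud, 38811 for any month, 19394, 28535 and 27489 for the seasonal contrasts, 113446 over the steps, 152085 over sites within months, 17703 and 10284 for the later 2 site differences, 2739 for April, 15972 for site means, 14411 for the leaf collections and 14737 for leaf change minus bud change. It also turned the split of October minus July to 57.8% rising and that of leaf collection 4 minus 1 from 47.3% to 67.8%, and brought January minus October to 49.5% rising.

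The 2 trees of a single library series gave 9226 for any month in buds, 385, 4994 and 874 for the seasonal contrasts and 25 over the steps. This fit had fewer libraries and 1 mean per month for both sites, so differences between the sites entered the spread. Its lower counts cannot be put down to the series or to the number of libraries alone. The site differences could not be tested in them, with 1 tree per site, and the gene list alternatives were not run. The collection number in place of the month gave 4378 for March minus January, 9037 over the monthly steps and 11271 for the site difference of March minus January. Fukuoka had an added collection on 29 August, so later dates there moved, with 14 February and 19 December for March and January. These counts therefore compare other months in Fukuoka and do not show how firm the March result is. Leaving out each tree in turn, where the lone tree of a site is assumed to vary like the others, gave 14338 to 14847 for leaf minus bud, 23011 to 23416 for any month, 3318 to 3565, 9201 to 9522 and 8321 to 8616 for the seasonal contrasts, and 13828 to 14274 over the steps. It gave 53693 to 61738 over sites within months, 11212 to 14963, 9531 to 11456 and 3461 to 5901 for the site differences (3461 without Fukuoka replicate 1, 3847 without Fukuoka replicate 2), 526 to 903 for April (526 without Hokkaido replicate 2), 924 to 1367 for site means, 3235 to 3623 for the leaf collections and 4318 to 4925 for leaf change minus bud change. Without Tsukuba, an alternative chosen after seeing the data, October minus July called 4832 genes, 45.9% of them rising against 35.8%, and January minus October 10097. Of the values of named genes under other settings, 598 kept direction and call and 18 kept direction only.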

Other observations

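Of the 23018 genes that changed between months, the month of the highest mean was the same in Tsukuba and Fukuoka for 45.2%, in Hokkaido and Fukuoka for 38.5% and in Hokkaido and Tsukuba for 37.8%, and it lay within 1 month for 68.3%, 65.2% and 66.4%. Between single trees the month was the same for 54.6% to 61.6% of the genes in the 3 pairs of one site, and for 32.4% to 45.0% in the 12 pairs of different sites. October held the highest mean of 10.4% of these genes in Hokkaido, 7.75% in Tsukuba and 4.87% in Fukuoka. Months of the highest mean were taken from levels as deposited. IDs with SPA held 51.8 ± 0.193% of the TPM in buds and 51.0 ± 0.112% in leaves of the first 4 collections (SD over 6 trees). By month, the bud share ran from 51.0 ± 0.734% in December to 52.1 ± 0.762% in February.

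The count limited to months whose closest date differed, its spread and the overlap of genes were added after the result was seen, and the reading of the test was changed more than once after that. Differences between sites within a month may partly be shifts in timing, a hypothesis tested with a prediction set before: the Fukuoka date closest to each collection was chosen on alternate genes, and calls were counted on the other 20080. Both sets of genes come from the same libraries, so fewer calls at the closest date are likely in any case. If timing were the main reason, at most 50% as many calls would be found at the closest date. Summed over 10 months, 66.9% as many were found for Hokkaido (9239 against 13800) and 74.5% for Tsukuba (8169 against 10958), over that bound at both sites. In 4 months for Hokkaido and 7 for Tsukuba, however, the closest date was that of the same month, so the count could not change. Over the other months the mean share per month was 56.0% (SE 15.7, 6 months) for Hokkaido and 59.8% (SE 6.14, 3 months) for Tsukuba, both within 2 SE of the bound. Of the calls in the same month, 2221 of 9447 for Hokkaido (23.5%) and 1494 of 6312 for Tsukuba (23.7%) were the same genes in the same direction at the closest date, and most calls there were other genes, 2665 of 4886 and 2029 of 3523. These shares of the same genes were not compared with those at a date that does not match, so they give no direction. Timing as the main reason therefore cannot be told apart from other differences between the sites. The months differed: Hokkaido buds of August went from 1466 to 65 calls and Tsukuba buds of October from 3502 to 1673, but Hokkaido buds of December went from 1113 to 1050 and of February from 1649 to 1587.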
